A study of Homo sapiens with 7 samples.

How the data were processed

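The series held 3 single-cell RNA libraries and 4 chromatin immunoprecipitation samples from cardiac cells grown out of H1, an established human embryonic stem cell line. The single-cell libraries came from day 11 of differentiation, from day 15 with the vehicle DMSO and from day 15 with CHIR, the usual short name of CHIR99021, an inhibitor of the kinase GSK3 that activates canonical Wnt signalling. Each of these groups had 1 library. The labels gave no treatment for day 11, and neither a dose nor a time of addition for CHIR. The immunoprecipitation samples were H3K27ac, a histone mark of active promoters and enhancers, and input chromatin from day 15 CHIR cells, with replicates 1 and 2 of each.

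Per the labels' protocols, the tissue was dissociated with collagenase and Accutase, live cells were sorted by exclusion of the dye DAPI, and droplet libraries were made that count the ends of transcripts with unique molecular identifiers (UMIs). The same protocol text names day 15 for the day 11 sample too. Per the submitters' processing notes, the single-cell reads were processed with Cell Ranger 6.1.1 on GRCh38, and the notes of the day 11 sample also name R 4.1.0 and Seurat 4.3.0. Whether reads in introns were counted is not given in the sources used here. The authors deposited each library as a table of raw whole-number UMI counts per gene and cell, not normalised. The deposited cells had already been filtered by the authors on the number of genes, since cells held between 1811 and 5999 genes at day 11, between 1804 and 5990 with DMSO and between 1802 and 5994 with CHIR. The tables listed 26940, 22469 and 23503 genes in that order, of which 21262 were listed in all 3.

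The H3K27ac file was a peak list that the labels describe as merged over both replicates, made with Bowtie2 and MACS2 on hg19, per the submitters' processing notes. For each peak the authors deposited a score, a fold enrichment as a linear ratio, and a p-value and a q-value as −log10 values. The deposited score equalled 10 times the −log10 p-value rounded down for 99.9% of the peaks. These values describe and rank peaks within this list only. No hg19 annotation was used here, so no gene was assigned to a peak and the planned test of promoters of listed genes was not run. Input chromatin was not analysed here.

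Cells were kept with at least 500 genes, at least 1000 UMIs and at most 25% mitochondrial counts, which removed 0 cells. Doublets were called per library with Scrublet, as built into scanpy 1.11.5, at an expected rate of 0.06. It called 220 cells (5.48%) of the DMSO library, which were removed, but 1 cell at day 11 and 0 cells with CHIR, so it did not work in the last 2 libraries and doublets stayed in them. The cells kept numbered 5682 at day 11, 3795 with DMSO and 5607 with CHIR.

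All 3 libraries were clustered together. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen with library as batch, and 30 principal components and 15 neighbours were followed by Leiden clustering at resolution 0.6, with no integration and seed 1. Genes of 7 lists to be compared (regulators of the atrioventricular canal, slow conduction, sinoatrial, fast conduction, atrial and ventricular genes, and Wnt targets) were kept out of the variable genes unless they were cardiomyocyte markers. A cluster was named from fixed markers of 9 cell types. Markers counted if they reached 20 CPM (UMIs scaled to a common library total) in some cluster, and a cell type needed at least 3 of them. The level used was the median over markers of the CPM relative to the cluster where each was highest. A cluster was called mixed when cardiomyocyte markers reached 0.2 and mesenchymal markers 0.15, cardiomyocyte-like (CM-like) when only the former did and reached 0.35, and mesenchymal-like when only the latter did. Other types needed 0.5, and endothelial or endoderm markers at that level went before mixed and mesenchymal names. Smooth muscle was not given as a name, and its markers only counted against other names. A cluster stayed unnamed when its 10 leading genes held more markers of another type, or when its median UMIs were under the library median divided by 3 and no marker of its name was among them.

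For each comparison, raw UMIs were summed per gene over the cells of a class and divided by the sum of all UMIs of those cells, giving CPM. The ratio of 2 CPM values has an exact conditional binomial (Clopper-Pearson) 95% interval, and log2 ratios had 0.5 added to each count. Shares of cells have exact binomial 95% intervals. All intervals cover counting error only. With 1 library per group no difference has a replicate check, and no p-value, standard error or number of changed genes is given. Ratios were taken for genes listed in both tables with at least 20 UMIs over the 2 libraries.

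The genes named were fixed by rule. These were 16 genes whatever their values, of which 1 is not reported here, and genes of at least 50 CPM in the higher library, ranked by the interval bound nearest to 1, the first 12 higher and the first 12 lower. Mitochondrial and ribosomal protein genes and genes of the sex chromosome checks were left out of the ranking. Up to 4 members of each gene list with the largest ratio, at 10 CPM or more, were added. The 32 gene lists covered regions of the heart, signalling pathways, contraction, metabolism, stress and other cell types. Some genes are in several lists, such as NPPA (atrial and fast conduction) and MYL7 (atrial and sarcomere), so the lists are not independent of each other. For each list, members at least 1.5-fold higher or lower were counted, and the median log2 ratio was ranked among 10000 random lists of the same size matched on CPM in 20 bins. Those percentiles are a description of these libraries. For shares of cells with a UMI of 12 genes, each CM-like cell was thinned to 7311 UMIs, the 10th percentile, and shallower cells were left out.

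The designs, lists, markers, naming rule and most alternatives were chosen before the data were examined. The relative levels used to name clusters, the mixed class, the rule that an alternative needs at least 20 cells of a class and the genes followed through the alternatives were set after clusters and marker levels had been seen. Alternatives chosen beforehand were 3 other scalings (the mean of per-cell CPM, totals without mitochondrial and ribosomal protein genes, and TMM factors from edgeR 4.0.16), other cell filters, doublets kept, thinning, Leiden resolutions of 0.3 and 1.0, libraries clustered alone, list genes kept in the clustering, members of at least 200 UMIs, stricter peaks and merged peaks. Removal of the 6% highest doublet scores per library, removal of a gene length trend in 20 bins, mixed clusters counted as CM-like, and cluster 10 left out of the CM-like class were added after seeing the data. Gene spans came from a RefSeq gene table and were used for lengths only.

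The ratio and list steps were tested on simulated counts, drawn with Poisson noise from the mean profile of each pair of libraries at a fraction of their depth. This is the noise that the intervals assume, so the test says nothing on further variation between cells or libraries. For CHIR against DMSO, intervals held the true ratio for 95.9% of 16076 unchanged genes, and folds of 2 and 4 were recovered as medians of 1.99 and 4.03. For DMSO against day 11 (17631 unchanged genes) the share was 95.7%, and for CHIR against day 11 (17923) it was 95.6%. Computations used python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3.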

Results

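Single-cell transcriptomes of H1-derived cardiac cells were available from day 11, from day 15 with DMSO and from day 15 with CHIR, 1 library each. The series title places the work in the specification of atrioventricular canal (AVC) cardiomyocytes by canonical Wnt signalling, so the comparisons ask how AVC, chamber and Wnt genes stood in the CHIR library. The libraries held 75906387 UMIs in 5683 cells at day 11, 65675862 in 4015 cells with DMSO and 81076689 in 5607 cells with CHIR. The median cell had 12689, 15250 and 12687 UMIs, and 4367, 3644 and 3346 genes, in the same order. Ribosomal protein genes took 15.1%, 24.2% and 31.6% of the UMIs, and the median mitochondrial share was 2.504%, 3.67% and 4.55%. No difference between these libraries has a replicate check, and every interval covers counting error only.

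Heart muscle cells made up most of the day 11 library and a minority of the CHIR library. CM-like cells, which carried troponin, myosin and NKX2-5 transcripts, were 3421 of 5682 cells at day 11 (60.2%, interval 58.9 to 61.5). They were 1918 of 3795 cells with DMSO (50.5%, 48.9 to 52.1) and 1318 of 5607 with CHIR (23.5%, 22.4 to 24.6). Mesenchymal-like cells, which carried collagen genes, POSTN, LUM or DCN, were 3701 cells with CHIR (66.0%), 676 with DMSO (17.8%) and 5 at day 11 (0.0880%). The clusters behind that name were almost separate, with 5 day 11 cells beside 674 DMSO cells in cluster 7 and 2 DMSO cells beside 1983 CHIR cells in cluster 13, so genes were not compared within it. Endoderm-like cells with TTR, APOA2 and AFP were 298 (5.24%), 106 (2.79%) and 76 (1.36%) at day 11, with DMSO and with CHIR. Endothelial-like cells with PLVAP and EMCN were 76 (1.34%), 32 (0.843%) and 36 (0.642%).

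Cells that carried both muscle and mesenchymal transcripts at high level were kept apart as mixed by a threshold set after the data were seen. They were 433 cells at day 11 (7.62%), 476 with CHIR (8.49%) and 0 of 3795 with DMSO, where the interval ends at 0.0972%. Without the 6% highest doublet scores, 0 cells were mixed at day 11 and 4.17% with CHIR, and with list genes kept in the clustering 0 cells were mixed at day 11. Unnamed clusters held 1449 cells at day 11 (25.5%) and 1063 with DMSO (28.0%). The largest day 11 cluster without a name was led by NPPB, TAGLN and TNC, and the one of the DMSO library by STMN2, SFRP5 and TCF21. Both clusters, of 1363 and 1066 cells, reached the mesenchymal marker level and went without that name only because markers of other types were among their leading genes, so the mesenchymal-like shares at day 11 and with DMSO depend on that rule. No cluster was named epicardial, neural, pluripotent or blood, and smooth muscle was not among the names that could be given. All shares are of cells that passed a live-cell sort and the authors' bounds on genes per cell, and doublets could not be called in the day 11 and CHIR libraries. With doublets kept, the CM-like share with DMSO was 40.9% and 456 of 4015 cells (11.4%) were mixed, and at Leiden resolution 0.3 the CM-like share with CHIR was 0.0713%, or 4 cells, while 1783 CHIR cells (31.8%) and 1 day 11 cell were mixed.

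**Figure D1:**
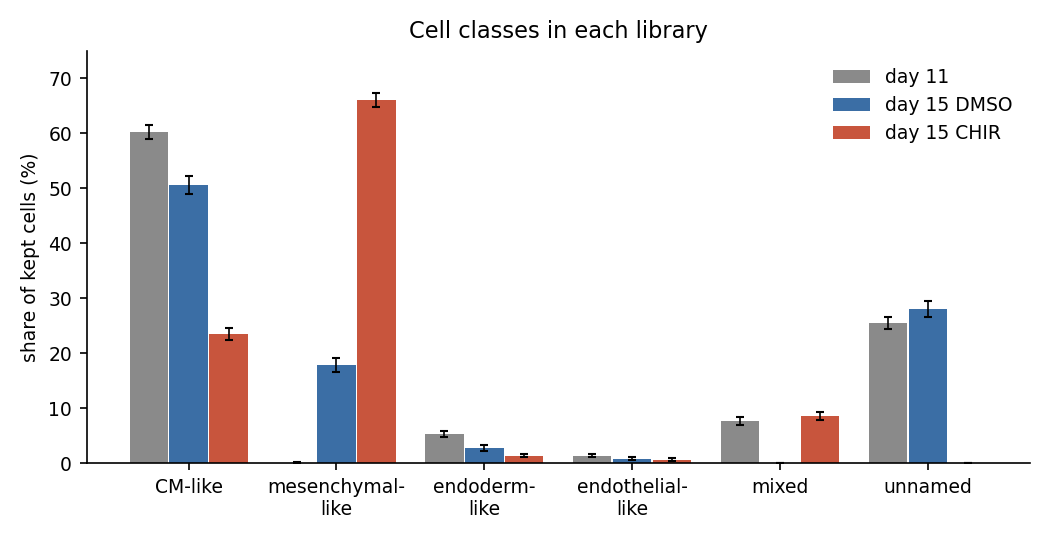
Share of kept cells in each named class, in percent, for the day 11, day 15 DMSO and day 15 CHIR libraries, with exact 95% binomial intervals of counting error. CM-like cells were 60.2%, 50.5% and 23.5% of the 3 libraries, and mesenchymal-like cells 66.0% with CHIR.

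Canonical Wnt target genes and 5 of 10 AVC regulators were higher with CHIR than with DMSO in CM-like cells at day 15. Most ventricular genes were lower, and so were 4 AVC regulators, BMP2 and RSPO3 among them. AXIN2, a feedback inhibitor and classic readout of canonical Wnt signalling, was at 69.6 CPM with CHIR and 3.19 with DMSO, 21.8-fold higher (17.4 to 27.7). The Wnt-responsive transcription factor LEF1 was 5.80-fold higher (5.17 to 6.53). TBX2 and TBX3, T-box repressors that keep AVC muscle from taking on chamber identity, were 1.83-fold (1.70 to 1.97) and 2.29-fold higher (2.02 to 2.60). NPPA, the atrial natriuretic peptide of working chamber muscle, was 8.24-fold lower (7.63 to 8.91), at 37.2 against 307 CPM.

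The comparison was between 1318 CHIR cells with 19093636 UMIs and 1918 DMSO cells with 25062848. The class consisted of clusters 12 and 17 in the CHIR library, with 12 cells of cluster 10, and of clusters 9, 10 and 11 in the DMSO library. USP18, EMC10, KCNG1, IRX2 and OSR1, which rank high below, and GJA5 also lead cluster 12. HAMP, NPPA and TNNC1, lower with CHIR, lead DMSO cluster 9, and SHOX2, NPPA, PLN and MYL7 lead cluster 10, so their ranking is not independent of the clustering. Cluster 10, with 273 DMSO cells, also carried epicardial, mesenchymal and sinus node genes, so results that move without it are given below with the value from the 1306 CHIR and 1645 DMSO cells left, a test chosen after the result was seen. Across 15755 genes the median log2 ratio was −0.03. It was 0.14 with mitochondrial and ribosomal protein genes left out of the totals. The log2 ratio rose somewhat with gene length, with a Spearman correlation of 0.17 across genes here, 0.26 in endoderm-like and 0.38 in endothelial-like cells, and medians of the longest genes of 0.13, 0.62 and 0.89.

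USP18, an enzyme that removes the ubiquitin-like modifier ISG15, had the highest rank among the genes higher with CHIR, at 224 against 9.06 CPM, a ratio of 24.7 (21.6 to 28.4). KCNG1, a modifier subunit of voltage-gated potassium channels, was 16.1-fold higher (14.7 to 17.7). OSR1, a zinc finger factor of early mesoderm and the second heart field, was 13.6-fold higher (11.4 to 16.3). GAS5, a long noncoding RNA that hosts small nucleolar RNAs, was at 1541 against 156 CPM, 9.86-fold higher (9.53 to 10.2). The host genes SNHG19 and SNHG3 were 8.30-fold and 6.25-fold higher. ADAMTS19, a secreted protease expressed in developing heart valves, was 9.18-fold higher (8.41 to 10.0). EMC10, a part of the membrane protein insertion complex of the endoplasmic reticulum, the matrix proteoglycan gene SPOCK1, the Iroquois factor IRX2 and the actin-binding kinase substrate MARCKS were 7.88-fold, 7.35-fold, 7.002-fold and 5.72-fold higher.

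Among the genes lower with CHIR, RSPO3, a secreted amplifier of Wnt signalling, stood at 4.29 against 127 CPM, 29.6-fold lower (23.8 to 37.4). The extracellular superoxide dismutase SOD3 was 29.4-fold lower, HAMP, which encodes the iron hormone hepcidin, 23.6-fold, and the semaphorin receptor NRP2 20.8-fold. MYL7, the atrial myosin light chain that all early heart muscle expresses, was 11.2-fold lower (11.0 to 11.3), at 2070 against 23086 CPM. The slow myosin heavy chain MYH7 was 19.0-fold lower (15.2 to 24.0). ANKRD1, a stretch-responsive sarcomere protein, was 17.5-fold lower (7.74-fold without cluster 10). COX6A2, the muscle form of a cytochrome oxidase subunit, and PDLIM3, a Z-disc protein, were 13.4-fold and 11.98-fold lower, the latter 2.45-fold without cluster 10. The small heat shock protein gene HSPB2 and the calcium-binding protein gene TESC were 10.3-fold and 9.56-fold lower.

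Of the 10 AVC regulators, 5 were at least 1.5-fold higher and 4 at least 1.5-fold lower, with a median log2 ratio of 0.71 and a mean of 0.01. With TMM factors 6 were higher and 3 lower, and without cluster 10 the counts were 5 and 3. The median lay at percentile 99.8 of random lists. BMP4, a ligand of the BMP family, was 2.41-fold higher (7.46-fold without cluster 10), and MSX2, a homeobox target of BMP signalling in the canal, 1.46-fold higher (1.35 to 1.58). BMP2, the main BMP ligand of AVC muscle, was 2.98-fold lower (2.74 to 3.24). Of 15 measured Wnt targets, 9 were higher and 2 lower, with a median of 1.45 and percentile 100. NKD1, an intracellular Wnt antagonist, was 21.3-fold higher (12.6 to 38.6), and the secreted antagonist DKK1 was 8.10-fold lower, but its ratio was 1.19 (0.892 to 1.60) without cluster 10. TBX3, MSX1, NKD1 and SP5 were highly expressed in mesenchymal-like CHIR cells, and dropped below 1.5-fold when the largest share of mesenchymal marker RNA seen in CM-like cells, that of COL1A1, was taken off. With the median marker share taken off, TBX3, NKD1 and SP5 stayed 2.03-fold, 8.03-fold and 3.06-fold higher, and MSX1 was at 1.15. Of 11 Wnt ligands and secreted antagonists, 2 were higher and 4 lower (3 and 4 with TMM factors), with a median of −0.29 and a mean of 0.03. The antagonists SFRP1 and SFRP5 were 3.53-fold and 2.67-fold lower, though SFRP5 had a ratio of 0.983 (0.833 to 1.16) without cluster 10.

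Of 8 sinoatrial regulators, 6 were lower and 1 higher, with a median of −2.65, or −0.95 over members of at least 200 UMIs. This rests on cluster 10, since without it 5 were measured, 1 was higher and 2 lower, and the median was −0.20. SHOX2, a homeobox factor of the sinus node, had 6 UMIs with CHIR and 348 with DMSO, of which 344 lay in cluster 10. It was 44.2-fold lower with CHIR (20.1 to 121), but without cluster 10 the direction turned, and 6 against 4 UMIs gave a ratio of 1.67 (0.395 to 8.03). ISL1, a factor of the second heart field and sinus node, was 8.45-fold lower, and 3.55-fold (2.78 to 4.56) without that cluster, while the ligand BMP5 was 2.03-fold higher. Of 9 fast conduction and chamber genes, 7 were lower and 2 higher, with a median of −0.99. NPPB, the brain natriuretic peptide, was 3.85-fold lower (1.63-fold without cluster 10). The gap junction genes GJA5 and GJA1 were 7.83-fold (6.60 to 9.35) and 1.55-fold higher (1.23 to 1.95). Of 10 atrial genes, 5 were lower and 0 higher, with a median of −0.81; leaving mitochondrial and ribosomal genes out of the totals gave 5 and 1, and leaving cluster 10 out 4 and 2 with a median of −0.30. The calcium pump regulator SLN was 24.3-fold lower. Of 10 ventricular genes, 7 were lower and 2 higher, with a median of −1.11. The ventricular light chain MYL2, the repressor HEY2 and the LIM protein FHL2 were 3.59-fold, 3.48-fold and 3.29-fold lower, whereas the ventricular factor IRX4 was 1.74-fold higher (1.63 to 1.86). Of 9 slow conduction and pacemaking channels, 2 were lower and 1 higher, with a median of −0.01. It turned to 0.16 without mitochondrial and ribosomal genes and 0.04 with TMM factors, and with the mean of per-cell CPM it stayed at −0.01 with 2 higher and 2 lower. The pacemaker channel HCN4 was 1.87-fold lower (1.68 to 2.07), and KCNJ5, an acetylcholine-gated potassium channel, 2.23-fold higher.

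**Figure D2:**
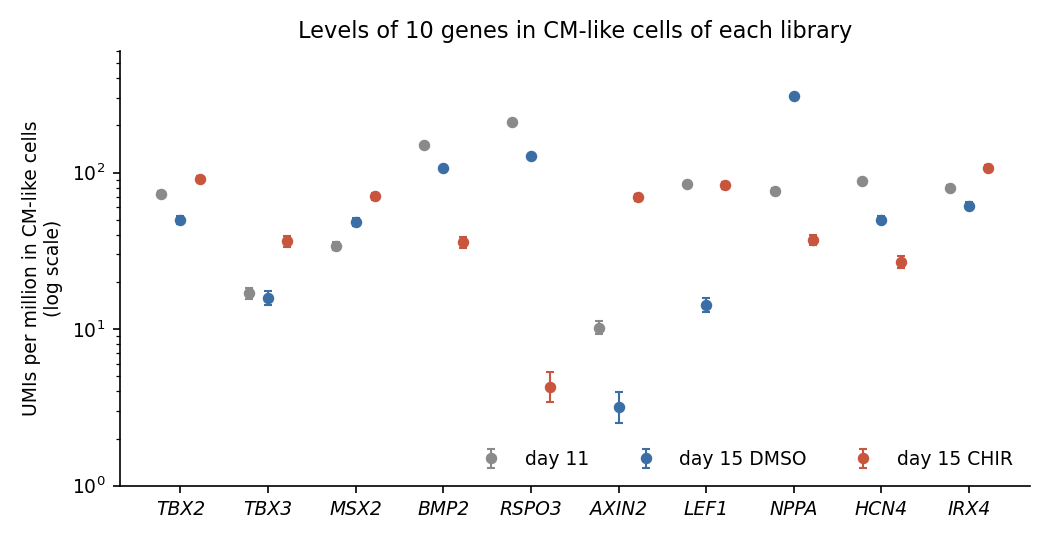
CPM of genes fixed by name in CM-like cells of the day 11, day 15 DMSO and day 15 CHIR libraries on a log axis, with exact 95% intervals of counting error. AXIN2 stood at 69.6 CPM with CHIR against 3.19 with DMSO, and RSPO3 at 4.29 against 127.

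Of 18 sarcomere genes, 9 were lower, 1 higher and 8 between, with a median of −0.68 against −0.17 in random lists. The troponin C and tropomyosin genes TNNC1 and TPM1 were 2.54-fold and 2.48-fold lower, while TNNT2 was 1.24-fold higher (1.23 to 1.26). Of 10 calcium handling genes, 5 were lower and 0 higher, with a median of −0.51 at percentile 5.45 of random lists. The counts were 4 and 0 with TMM factors, and 3 and 0 without mitochondrial and ribosomal genes. The calcium pump ATP2A2 and its inhibitor PLN were 1.56-fold and 1.85-fold lower. Of 10 cardiac transcription factors, 1 was higher and 1 lower (2 and 1 without mitochondrial and ribosomal genes), with a median of −0.23, and NKX2-5 had a ratio of 0.856. Of 8 early cardiac mesoderm genes, 6 were lower and 2 higher, with a median of −2.11. MESP1, a factor of the first cardiac mesoderm, and the receptor PDGFRA were 4.81-fold and 3.88-fold lower, and the receptor KDR 3.77-fold higher.

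In signalling lists, 5 of 8 BMP targets were lower and 0 higher (4 and 1 without mitochondrial and ribosomal genes), with a median of −0.80. ID3, an inhibitor of helix-loop-helix factors induced by BMP, was 4.25-fold lower, at 171 against 727 CPM, and the inhibitory SMAD6 2.97-fold lower. Of 5 Notch targets, 4 were lower and 1 higher, with a median of −0.99, with HES4 4.01-fold lower and the ligand JAG1 2.04-fold higher. Of 7 retinoic acid targets, 3 were lower and 2 higher (2 and 2 without mitochondrial and ribosomal genes), with a median of −0.21. Stress lists stood on the other side. Of 7 genes of the integrated stress response, 4 were higher and 0 lower, with a median of 0.90 and percentile 99.8. CHAC1, which degrades glutathione, was 11.5-fold higher (8.62 to 15.5), and the transcription factor ATF4 1.86-fold higher. Of 7 p53 targets, 5 were higher and 0 lower, with a median of 0.86 and percentile 99.7, among them the cell cycle inhibitor CDKN1A at 2.34-fold and the p53 ubiquitin ligase MDM2 at 2.49-fold. Of 10 immediate early and dissociation genes, 2 were higher and 2 lower (3 and 1 without mitochondrial and ribosomal genes), with a median of −0.36.

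Of 16 cell cycle genes, 4 were higher and 2 lower with a median of 0.21, but 4 and 5 without cluster 10, with a median of 0.06. The replication licensing gene MCM3 was 3.12-fold higher and the mitotic kinase CDK1 2.01-fold lower. Of 11 glycolysis genes, 3 were higher and 1 lower, with a median of 0.34, and PFKP and PKM were 2.74-fold and 1.83-fold higher. Oxidative phosphorylation had 0 of 11 higher and 2 lower, with a median of −0.31. With the mean of per-cell CPM 1 was higher and 2 lower. Of 10 fatty acid oxidation genes, 1 was higher and 3 lower, and without mitochondrial and ribosomal genes 2 and 2. Their median of −0.15 changed sign between scalings.

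Markers of other cell types were read in the CM-like cells as well, and several of their medians turned when cluster 10 was left out. These were then 0.11 for epicardial markers (4 measured, 1 higher and 1 lower), 0.17 for smooth muscle markers (3 and 2), 0.06 for cushion genes (2 and 2) and 0.20 for fibroblast and mesenchymal markers (4 and 2). Of 9 cushion and EMT genes, 2 were higher and 1 lower (2 and 2 with the mean of per-cell CPM), with a median of −0.11 that changed sign between scalings and a mean of 0.15. The matrix protein POSTN was 5.47-fold higher, but its 24.9 CPM are 3.37% of the 739 CPM in mesenchymal-like CHIR cells, below the median marker share of 4.12%, so free RNA is not excluded for it. Extracellular matrix had 0 of 11 higher and 4 lower (1 and 4 with the mean of per-cell CPM), with a median of −0.21 and fibronectin, FN1, 3.06-fold lower. Of 6 epicardial markers, 5 were lower and 1 higher, with a median of −1.41 that turned positive without cluster 10. Fibroblast and mesenchymal markers had 2 of 10 higher and 3 lower (3 and 3 with the mean of per-cell CPM), with a median of −0.03 that changed sign between scalings and was 0.02 over members of at least 200 UMIs, and positive without cluster 10. Of 5 endothelial markers, 3 were higher and 2 lower (3 and 1 without mitochondrial and ribosomal genes), with a median of 0.95 (0.51 without cluster 10, with 2 and 2) that turned to −0.75 over members of at least 200 UMIs. Of 7 smooth muscle markers, 3 were lower and 1 higher, with a median of −0.27 that turned positive without cluster 10, and the actin-binding protein TAGLN was 4.26-fold lower (2.27-fold without it). Endoderm markers had 2 of 4 higher and 2 lower with a median of 0.55 that turned to −1.69 over members of at least 200 UMIs, neural markers 0 of 2 higher and 2 lower with a median of −3.26 (without cluster 10, 1 measured gene at −0.22), and pluripotency markers 0 of 4 higher and 2 lower with a median of −0.62. No blood marker reached the minimum of 20 UMIs in CM-like cells.

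**Figure D3:**
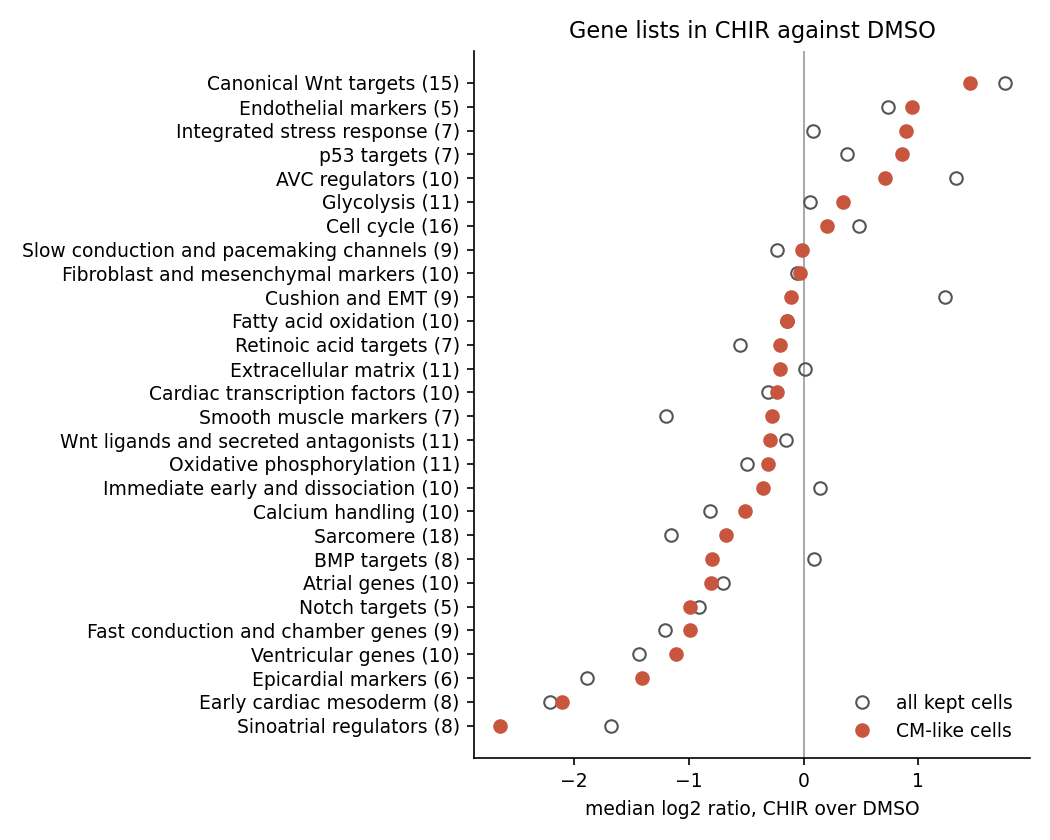
Median log2 ratio of gene lists for CHIR over DMSO at day 15, in CM-like cells and in all cells. Endoderm, neural, pluripotency and blood markers, with few or no measured members in CM-like cells, are not drawn. Wnt targets stood at 1.45 and 1.75 and sinoatrial regulators at −2.65 and −1.68, where leaving cluster 10 out gave −0.20 in CM-like cells.

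After each CM-like cell was thinned to 7311 UMIs, TBX2 was seen in 46.9% of CHIR cells, 26.0% of DMSO cells and 37.7% of day 11 cells. TBX3 was seen in 21.7%, 9.98% and 10.1%, MSX2 in 38.3%, 24.9% and 18.3%, and AXIN2 in 39.5%, 2.07% and 7.20%, in the same order. LEF1 had 45.1%, 8.94% and 42.1%, IRX4 52.3%, 31.8% and 34.1%, BMP2 15.8%, 36.0% and 49.5%, and RSPO3 2.37%, 26.3% and 47.4%. HCN4 had 17.5%, 29.0% and 44.4%, NPPA 15.5%, 33.2% and 19.8%, MYL2 3.19%, 8.15% and 1.98%, and SHOX2 0.245%, 4.32% and 0.0320%. Both TBX2 and TBX3 were seen in 10.5% of CHIR cells against 10.2% from the product of the single shares. With DMSO these values were 3.22% and 2.60%, and at day 11 they were 3.97% and 3.82%. Long genes stood higher in the day 11 library, as given below. Thinning does not remove this, so differences of day 11 shares from day 15 may hold part of it.

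The shares rest on 1223 CHIR, 1644 DMSO and 3124 day 11 cells, after 95, 274 and 297 shallower cells were left out, and the classes had medians of 14007.5, 12821 and 11453 UMIs. Unthinned, TBX2 was seen in 65.3% of CHIR and 40.5% of DMSO cells. In endoderm-like cells, with medians of 19141, 20766 and 15263 UMIs in the CHIR, DMSO and day 11 libraries, TBX2 was seen in 3.95%, 1.92% and 7.82% of thinned cells, and IRX4 in 0, 0.962% and 1.02%. RSPO3 was seen there in 1.32%, 7.69% and 10.2%, so that its share in CHIR CM-like cells lay near background. TBX3 and MSX2 were seen in 39.5% and 67.1% of endoderm-like CHIR cells, a class that expresses both, which therefore gives no background for them. In CHIR, DMSO and day 11 endoderm-like cells, LEF1 was seen in 39.5%, 4.81% and 7.82%, AXIN2 in 21.1%, 0 and 4.08%, and BMP2 in 2.63%, 10.6% and 19.7%. Wnt targets were also higher in endoderm-like CHIR cells, so that class gives no background for LEF1 and AXIN2 with CHIR. HCN4 was seen there in 0, 0 and 1.36%, NPPA in 0, 2.88% and 0.340%, MYL2 in 0, 0.962% and 0.340%, and SHOX2 in none.

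When all cells of the 2 day 15 libraries were compared, Wnt feedback genes and cushion genes were higher with CHIR, and most epicardial, endoderm and sarcomere genes lower. NKD1 was at 139 CPM with CHIR and 0.869 with DMSO, a ratio of 159.9 (122 to 214). AXIN2 was 27.9-fold higher (23.4 to 33.5), LEF1 8.67-fold and SP5, a direct Wnt target factor, 93.5-fold (55.6 to 171). POSTN, a matrix protein of cushion mesenchyme and fibroblasts, was at 502 against 27.8 CPM, 18.1-fold higher (17.2 to 19.0). NPY, a neuropeptide, was 135-fold lower (96.2 to 195), and MYL7 was 14.5-fold lower (14.4 to 14.6).

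These sums were 81076689 UMIs of 5607 cells and 59847557 UMIs of 3795 cells, over 18672 genes with a median log2 ratio of 0.03, or 0.21 with mitochondrial and ribosomal protein genes left out. They mix changes in cells with the shares of cell classes given above. Further genes higher with CHIR were the carbonic anhydrase relative CA8 at 89.7-fold, the secretory granule protein CHGB at 36.2-fold, the homeobox factor PITX1 at 18.7-fold, USP18 at 16.5-fold, ADAMTS19 at 13.8-fold, the calmodulin-binding PCP4 at 10.2-fold, GAS5 at 10.1-fold and SPOCK1 at 8.55-fold. Lower were the protease inhibitor SERPINA1 at 32.2-fold, the visceral smooth muscle actin ACTG2 at 31.4-fold, HAMP at 31.1-fold, the transcription factor CEBPD at 29.5-fold and MGP, an inhibitor of calcification, at 25.1-fold. COX6A2, ANKRD1, SPP1, PDLIM3 and ASS1 were 19.7-fold, 19.5-fold, 17.3-fold, 16.0-fold and 14.6-fold lower.

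Of 16 Wnt targets, 13 were higher and 0 lower over all cells, with a median of 1.75. Of 10 AVC regulators, 6 were higher and 4 lower, with a median of 1.33. TBX3 was 6.87-fold higher (6.41 to 7.37), MSX1 6.69-fold, MSX2 2.95-fold and TBX2 2.55-fold, while RSPO3 was 13.5-fold and BMP2 3.95-fold lower. Of 9 cushion and EMT genes, 5 were higher and 0 lower, with a median of 1.23 and percentile 100; the mesenchymal factor PRRX1 was 7.51-fold higher and SNAI2 and TWIST1, drivers of epithelial-to-mesenchymal transition, 2.73-fold and 2.48-fold. Of 16 cell cycle genes, 8 were higher and 0 lower, with the proliferation marker MKI67 2.97-fold higher. Of 9 epicardial markers, 8 were lower and 0 higher, with the mesothelial gene UPK3B 41.0-fold lower. Of 9 endoderm markers, 7 were lower and 1 higher, with AFP 20.7-fold lower. Of 18 sarcomere genes, 12 were lower and 0 higher, with a median of −1.16. Fibroblast and mesenchymal markers had 2 of 10 higher and 3 lower (4 and 2 with the mean of per-cell CPM), with a median of −0.06 that changed sign between scalings. Smooth muscle markers had 4 of 7 lower and 0 higher, and the only measured blood marker had a log2 ratio of −2.24. NKX2-5 was 1.64-fold lower, TNNT2 1.17-fold lower, SHOX2 13.8-fold lower, GJA1 2.79-fold higher and IRX4 1.29-fold higher, though IRX4 had a log2 ratio of −0.19 with the mean of per-cell CPM.

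Between day 11 and day 15 with DMSO, smooth muscle type, fibroblast, stress, immediate early and cell cycle genes and some chamber genes stood higher in CM-like cells relative to the rest of the transcriptome. Part of this goes with gene length, since removing the length trend took the log2 ratio of NPPA from 2.003 to 1.16, left 4 sarcomere genes higher instead of 9 and turned MYL7 and TNNT2 to −0.22 and −0.20. Mixed day 11 cluster 3, led by GRIK1, ACTA1 and MYH11, was left out here, while DMSO had 0 mixed cells. Over all cells, the plain median of smooth muscle markers was 0.34 (3 higher and 1 lower), against 1.73 in CM-like cells. That of cell cycle genes was 0.10 (4 and 4), against 0.64, and that of p53 targets −0.08 against 0.40. Those of fibroblast, integrated stress and immediate early genes stayed positive, at 0.75, 0.85 and 0.52. NPPA was at 307 CPM at day 15 and 76.6 at day 11, a ratio of 4.01 (3.84 to 4.18), or 6.31-fold relative to the median of all genes. MYL2 had a ratio of 5.10 (4.15 to 6.31) and a relative fold of 8.01, and TAGLN, an actin-binding protein of smooth and immature heart muscle, a ratio of 6.54 (6.28 to 6.81) and a relative fold of 10.3, with a ratio of 3.50 without cluster 10. AXIN2 was 3.21-fold lower (2.52 to 4.13) and LEF1 5.91-fold lower (5.30 to 6.61), or 2.03-fold and 3.75-fold relative to that median.

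The day 15 DMSO sums (clusters 9, 10 and 11) were set against 3421 day 11 cells (clusters 0 and 1, with 3, 16, 2 and 1 cells of clusters 9, 10, 11 and 12) with 39586643 UMIs. The median log2 ratio of 17984 genes was −0.66, and −0.08 with TMM factors, so values relative to this median are given with the plain ratios. The log2 ratio moved with gene length, with a Spearman correlation of −0.61 across 15422 genes, which are not independent replicates. Of 5 bins by length, the longest genes had a median of −1.93 and the shortest of 0.13.

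**Figure D4:**
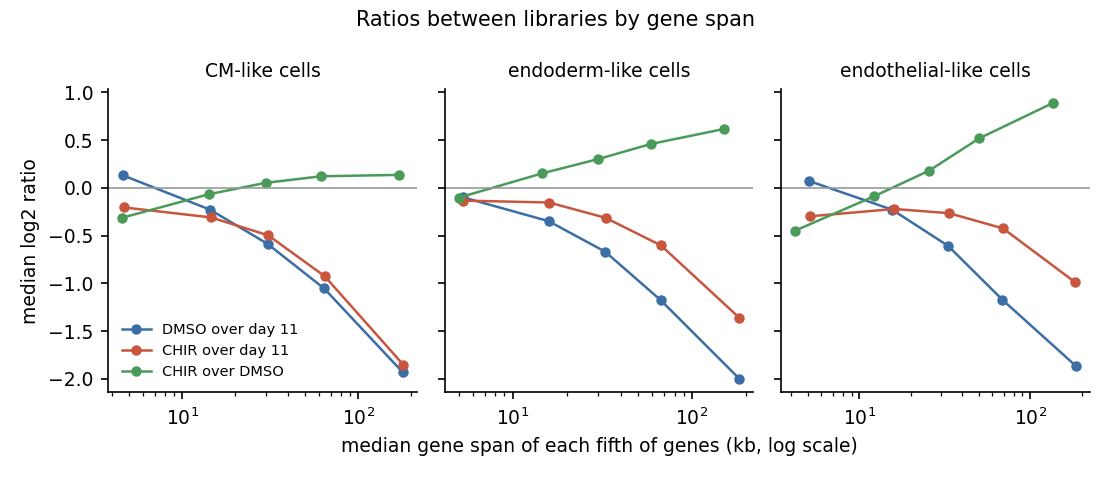
Median log2 ratio of genes in 5 bins of genomic span for DMSO over day 11, CHIR over day 11 and CHIR over DMSO, in CM-like, endoderm-like and endothelial-like cells. In CM-like cells the longest bin had medians of −1.93 for DMSO and −1.85 for CHIR over day 11, against 0.13 for CHIR over DMSO, which was 0.62 in endoderm-like and 0.89 in endothelial-like cells.

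HAMP was 15.3-fold higher with DMSO than at day 11 (13.6 to 17.2), and PDLIM3 13.7-fold (2.87-fold without cluster 10). The leucine-rich repeat gene LRRC75A, the cell cycle regulator SERTAD1, NPPB, the myosin light chain MYL9, MARCKS, CRIP2 and the skeletal actin ACTA1 had ratios from 6.46 down to 4.32, of which NPPB was at 2.12 and ACTA1 at 3.21 without cluster 10. SHOX2 had 348 UMIs at day 15 and 2 at day 11, a ratio of 275 (75.5 to 2278) that rests on cluster 10, since 4 and 0 UMIs were left without it. The genes ranked lower included clone-named transcripts and some channel genes. As a list, 9 slow conduction and pacemaking channels had 0 higher, 4 lower and 5 between relative to the median of all genes, and 6 lower by plain ratios. AC012574.1 had 2 UMIs at day 15 and 12846 at day 11. The synaptic adhesion gene NLGN1 was 67.8-fold lower, and the potassium channel genes KCNH7 and KCNQ5 59.9-fold and 58.5-fold lower. AC012574.1, NLGN1 and KCNH7 lead the day 11 clusters 0 and 1, so their ranking is not independent of the clustering. The cardiac factor TBX20 was 35.3-fold lower, the calcium channels CACNA1C and CACNA1D 17.1-fold and 10.4-fold, and the calcium release channel RYR2 14.3-fold. These plain folds were not separated from the gene length trend, in which the longest genes had a median log2 ratio of −1.93. The same holds for the slow conduction list, with a plain median of −1.06.

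Counts relative to the median of all genes hold part of the gene length trend. The shortest of 5 bins of genes by length had a plain median of 0.13 against −0.66 over all genes. A typical short gene therefore counts as higher by this measure, and random lists were matched on CPM, not on length. Relative to the median of all genes, 11 of 18 sarcomere genes were higher and 2 lower (9 and 6 by plain ratios), and 8 of 10 atrial genes were higher and 2 lower. In the ventricular list 6 of 10 were higher and 0 lower (5 and 1 by plain ratios), and in the fast conduction list 7 of 9 and 0 (6 and 2). All 7 smooth muscle markers and all 10 immediate early genes (7 by plain ratios) were higher, with relative medians of 2.39 and 1.74, and 5 smooth muscle markers with a median of 1.497 without cluster 10. Fibroblast and mesenchymal markers had 6 of 10 higher and 1 lower (5 and 2 by plain ratios) with a relative median of 1.29, and epicardial markers 6 of 9 and 2 (4 and 3) with 0.84, or 0.98 and 0.60 without cluster 10. Of 7 integrated stress response genes, 5 were higher and 0 lower (4 and 0 by plain ratios), and of 6 p53 targets 4 and 1 (3 and 2), with relative medians of 2.02 and 1.06. Over members of at least 200 UMIs the plain medians fell from 1.36 to 0.54 for the integrated stress response and from 0.40 to 0.06 for p53 targets, and turned from 0.19 to −0.47 for epicardial markers. Sinoatrial regulators had a relative median of 0.71 that turned to −0.42 without cluster 10. Of 16 cell cycle genes, 13 were higher and 0 lower (9 and 3 by plain ratios). Of 15 Wnt targets, 3 were higher and 4 lower (2 and 10 by plain ratios), with DKK1 8.32-fold higher, a difference that rests on cluster 10, without which the ratio was 0.887 (0.685 to 1.14). Of 10 AVC regulators, 4 were higher and 2 lower (2 and 3 by plain ratios), with a relative median of 0.36. TBX2, TBX3, BMP2 and RSPO3 had relative log2 ratios of 0.10, 0.56, 0.16 and −0.08. The plain log2 ratios were −0.55, −0.09, −0.50 and −0.73, and that of TBX3 turned to 0.05 without cluster 10. With TMM factors TBX2, TBX3 and BMP2 turned to 0.0253, 0.49 and 0.0801, and IRX4 went from −0.38 to 0.20. The atrial factor NR2F2 was 7.41-fold higher and SLN 7.18-fold, or 3.70-fold and 5.35-fold without it. Pluripotency markers had 4 of 5 lower and 0 higher.

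Between day 11 and day 15 with CHIR, stress, proliferation, smooth muscle and immediate early genes stood higher in CM-like cells and most calcium handling genes lower, relative to the median of all genes. Over all cells, the plain median of smooth muscle markers turned to −1.02 (1 higher and 4 lower), against 1.03 in CM-like cells. That of p53 targets fell from 1.28 to 0.15 (1 and 1). Those of cell cycle, integrated stress and immediate early genes stayed positive over all cells, at 0.64, 1.01 and 0.67. The calcium handling list had a plain median of −1.73, against −1.85 for the longest of 5 bins of genes by length. It was therefore not told apart from the gene length trend. AXIN2 had a ratio of 6.80 (6.08 to 7.62), or 11.6-fold relative to the median of all genes, and NKD1 10.3 (7.54 to 14.3). NKD1 stood in CHIR CM-like cells at 6.46% of its level in mesenchymal-like CHIR cells, so free RNA is not excluded for it. OSR1 was 28.1-fold (23.0 to 34.5) and MARCKS 25.5-fold higher (23.4 to 27.8). RSPO3 was 49.3-fold lower (39.7 to 62.1), and the secreted growth factors FGF8 and FGF10 were 106-fold (53.6 to 246) and 47.9-fold lower (29.4 to 84.0).

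The CM-like cells were those of the comparisons above, mainly clusters 12 and 17 against clusters 0 and 1, over 17816 genes with a median log2 ratio of −0.77, or −0.14 with TMM factors. The correlation with gene length was −0.43 across genes. USP18, SNHG19, GAS5, KCNG1 and LRRC75A were 18.0-fold, 17.4-fold, 15.7-fold, 14.7-fold and 14.6-fold higher, and SNHG3, IRX2, BASP1 and the stress-induced factor JUN 8.46-fold, 8.39-fold, 7.54-fold and 6.35-fold. Lower were AC012574.1 with 1 against 12846 UMIs, the phosphatase subunit PPP2R2B at 146-fold, ADAM28 at 137-fold, the potassium channel partners KCNIP2 and KCNIP4 at 105-fold and 60.6-fold, and TBX20 at 44.8-fold. USP18, KCNG1, IRX2, OSR1, AC012574.1 and PPP2R2B lead clusters of this comparison, so their ranking depends on the clustering. TBX3 and MSX2 were 2.15-fold (1.93 to 2.39) and 2.08-fold higher (1.93 to 2.24), TBX2 1.24-fold (1.17 to 1.32) and BMP4 4.79-fold. Across the settings run, log2 ratios went from 0.66 to 1.82 for TBX3 and from 0.49 to 1.68 for MSX2. Free RNA was not taken off in these settings, and TBX3 stood at 27.2% of its level in mesenchymal-like CHIR cells. BMP2, HCN4 and MYL7 were 4.21-fold, 3.30-fold and 7.24-fold lower. LEF1 had a plain log2 ratio of −0.03 and a relative one of 0.74.

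Relative to the median of all genes, 9 of 15 Wnt targets were higher and 1 lower (7 and 5 by plain ratios, with a plain median of 0.04). Of 10 AVC regulators, 6 were higher and 3 lower (4 and 3 by plain ratios), with a relative median of 1.15. All 16 cell cycle genes (12 by plain ratios) and all 7 integrated stress response genes were higher, the latter with a relative median of 2.15, and CHAC1 had a ratio of 31.0 (21.5 to 46.1). Of 7 p53 targets, 6 were higher and 0 lower (5 and 1 by plain ratios), with CDKN1A at 6.29-fold. Of 10 fibroblast and mesenchymal markers, 6 were higher and 2 lower (6 and 4 by plain ratios), and of 6 smooth muscle markers 6 and 0 (4 and 0), with relative medians of 2.06 and 1.80. The plain median of the former fell from 1.29 to 0.37 over members of at least 200 UMIs. POSTN, LUM and DCN stood in CHIR CM-like cells at 3.37%, 3.31% and 3.11% of their level in mesenchymal-like CHIR cells, so free RNA is not excluded for this list. Of 10 immediate early and dissociation genes, 8 were higher and 0 lower (6 and 1 by plain ratios), with 1.86, and of 8 epicardial markers 2 and 4 (1 and 6), with −0.53. The plain epicardial median went from −1.30 to −4.23 over members of at least 200 UMIs. Of 11 glycolysis genes, 10 were higher and 0 lower (4 and 1 by plain ratios). Of 10 calcium handling genes, 6 were lower and 1 higher (9 and 0 by plain ratios), with CACNA1C 16.1-fold and RYR2 11.9-fold lower by plain ratios. Of 9 early mesoderm genes, 6 were lower and 2 higher (7 and 1 by plain ratios). The sarcomere list was split, with 6 of 18 higher and 4 lower (2 and 8 by plain ratios). Many list medians of both day 11 comparisons changed sign between plain and TMM scaling, and the gene length trend stands beside each of these lists.

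H3K27ac, a mark of active promoters and enhancers, was mapped in day 15 CHIR cells as 1 merged list of 36596 peaks on hg19, 36585 of them on assembled chromosomes. The peaks had a median width of 381 bp (174 to 9125) and covered 21.6 Mb. Chromosome 1 held 3801 peaks and chromosome 19 held 2406. The authors' fold enrichment had a median of 5.69 and a maximum of 78.7, the smallest −log10 p was 5.02, and the median −log10 q was 11.0. The peak of highest −log10 q, 492, lay at chromosome 9, 137029545 to 137030578, with a fold of 78.7. Next came chromosome 9, 35657227 to 35659174 (fold 54.5), and chromosome 3, 187461947 to 187464129 (fold 65.8). The other peaks of the first 10 lay at chromosome 8, 79428161 to 79429055, chromosome 20, 52824278 to 52825289, chromosome 18, 3260914 to 3263201, chromosome 6, 52859487 to 52860465, chromosome 10, 32634989 to 32636791, chromosome 19, 33864171 to 33865625, and chromosome 1, 153606411 to 153607273.

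When peaks were joined across the gap usual in stitching enhancers, 15740 regions remained, of which 389 held 10 or more peaks. The region with most peaks, 65, lay at chromosome 17, 75368004 to 75495460, and spanned 127 kb. It was followed by chromosome 10, 80856706 to 80964252, with 60 peaks, and chromosome 1, 27845096 to 27933885, with 48. Peaks of both replicates had been merged before deposit and no peak list of another group was used, so the mark was not compared between replicates or conditions, and which genes lie at these positions was not analysed here.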

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

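The tests on nuclear RNA, on the mixed clusters and on free RNA were chosen only after the result was seen. AXIN2 moved in opposite directions from day 11 in the 2 day 15 libraries, with a log2 ratio of −1.67 with DMSO and 2.76 with CHIR in CM-like cells. The median of neural markers was 1.40 with DMSO, from 3 measured genes, and −2.76 with CHIR, from 1 measured gene, so different members stand behind it. Neither difference was tested, each arm had 1 library, and both arms share the day 11 library.

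Long genes stood higher in the day 11 library than in both day 15 libraries, and less strongly higher with CHIR than with DMSO (correlation 0.17 in CM-like and 0.26 in endoderm-like cells). More nuclear RNA in the day 11 cells is argued against by nuclear transcripts, whose median ratio of day 11 over DMSO was 0.900 (MALAT1 0.900, NEAT1 0.531, KCNQ1OT1 1.08). A change with time in cardiomyocytes alone is argued against by endoderm-like cells, where the correlation of log2 ratio with gene length was −0.36 for CHIR over day 11. For DMSO over day 11 it was −0.53 in the same cells, and a candidate explanation is that reads in introns were counted in the day 11 table, which leaves the trend between both day 15 libraries unexplained. A change with time in every cell type stays open, since time and library are the same split here.

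The mixed clusters of the day 11 and CHIR libraries carried muscle and mesenchymal genes together, and doublets were set against a cell state between both classes. At day 11 the second parent was 1396 unnamed cells, since only 5 cells there were named mesenchymal-like. In the CHIR library, 0 of 2439 genes stood above 1.5 times the higher parent class, so the cluster's profile is one that doublets could give. It correlated at 0.997 with a mixture of both parents whose weight was fitted to it, which does not separate doublets from a cell state. The cluster held 8.49% of the CHIR cells, above the expected rate of 6% set for all doublets. As its whole source, doublets would need a higher rate. The median UMIs were 0.913 of the sum of both parents, as doublets would give, but a cell state with much RNA is not excluded by this. The authors' upper bound on genes per cell removes the deepest cells and may have lowered this ratio. At day 11, 0.365% of genes stood above that level (13 of 3558, among them MYH11, ISL1 and ACTA1), and the median UMIs were 0.647 of the sum. Doublets and a cell state cannot be told apart there, since 39.3% of the cluster lay within 500 genes of the highest deposited cell, against 8.99% of all day 11 cells. Without the 6% highest doublet scores 0 cells were mixed at day 11, but this clustering also changed with other settings, as 0 were mixed with list genes kept in it.

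AVC regulators and Wnt targets stood higher in CHIR CM-like cells, next to many mesenchymal-like cells with high levels of some of them. Free RNA or doublets of those cells as the whole cause is argued against, since 10 of the 14 higher members stayed at least 1.5-fold higher after the largest marker share, 14.6%, was taken off. For TBX3, MSX1, NKD1 and SP5 the highest ratio left was 1.25, but with the median marker share of 4.12% taken off TBX3, NKD1 and SP5 stayed 2.03-fold, 8.03-fold and 3.06-fold higher and MSX1 was at 1.15. Free RNA and expression in muscle cells cannot be told apart for these genes, because the true share is not known. Wnt targets had a median log2 ratio of 2.96 in endoderm-like cells, with 12 of 12 higher, as a Wnt response beyond muscle cells would give. AVC regulators had a median of 0.14 there, with 2 higher and 3 lower. Free RNA of mesenchymal-like cells was not tested in endoderm-like cells, so that source stays open there. Treatment and library are the same split, so a difference between libraries stays open.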

How the results depend on the processing

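The removal of the 6% highest doublet scores, the gene length trend, mixed clusters counted in and cluster 10 left out were tests chosen only after the result was seen. In CM-like cells, CHIR over DMSO, 5 to 6 AVC regulators and 8 to 11 Wnt targets were higher under all settings run, with log2 ratios of 4.32 to 4.61 for AXIN2, 1.05 to 1.79 for TBX3, −3.71 to −2.93 for MYL7 and −1.78 to −1.25 for BMP2. Taking off free RNA was not among these settings. With the largest marker share taken off, the AVC regulators TBX3 and MSX1 and the Wnt targets NKD1 and SP5 dropped below 1.5-fold. NR2F2 turned from −0.25 to 0.11 with the mean of per-cell CPM, 0.12 thinned, 0.73 with doublets kept, 0.64 without the 6% highest scores, 0.74 with mixed clusters counted in and 0.767 without cluster 10. For DMSO over day 11, removing the length trend turned MSX2 to −0.30, MYL7 to −0.22 and TNNT2 to −0.20 and left 4 sarcomere genes higher (9 before), and TMM turned BMP2 to 0.0801 and TBX3 from −0.09 to 0.49. Wnt targets higher went from 2 to 1 without the length trend, with doublets kept, without the 6% highest scores and without cluster 10. With TMM, 4 Wnt targets (10 before) and 2 sarcomere genes (6 before) were lower. The CM-like share at day 11 was 62.2% at resolution 1.0, 61.7% with doublets kept, 58.1% clustered alone and 62.4% without the 6% highest scores. With DMSO it was 40.9% with doublets kept, 43.5% with list genes kept and 44.3% without the 6% highest scores, and with CHIR 0.0713% at resolution 0.3 and 24.7% without the 6% highest scores. For each of these, the cause was not tested. Unthinned cells hold more UMIs, so shares rose to 65.3% for TBX2, 34.7% for TBX3, 57.0% for MSX2 and 60.1% for AXIN2 with CHIR, and to 40.5%, 15.4%, 35.1% and 4.12% with DMSO. Merging peaks within 1 kb left 23306 by construction. The filter removed 0 cells, so its absence says nothing; at resolution 0.3 too few CHIR cells were left for a comparison, and the promoter test with its alternatives was not run. No paired analysis was possible because each single-cell group had 1 library and the immunoprecipitation replicates were used as 1 merged list.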

Other observations

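The tests on small nucleolar RNA host genes and on nonsense-mediated decay were written before their values were seen, and the test on doublets and the other values here were chosen only after the result was seen. A small set of DMSO cells in the CM-like class carried some genes of the sinus node, together with epicardial and mesenchymal genes. In cluster 10, with 273 DMSO cells, SHOX2 stood at 84.7 CPM against 0.0547 in the larger cluster 9. ISL1 stood at 148 against 16.3 CPM, TBX18, a factor of the sinus horn, at 13.8 against 1.15, and the atrial factor NR2F2 at 93.5 against 12.4. The hormone genes GHRH and TRH stood at 106 against 4.21 and 716 against 161 CPM, while the pacemaker channel HCN4 was at 48.5 against 51.8. TBX3, which the sinus node needs, was lower in cluster 10, at 7.38 against 16.4 CPM, and the chamber gene NPPA higher, at 405 against 294. TRH, GHRH and SHOX2 lead this cluster, so their levels are not independent of the clustering. The epicardial genes TCF21 and WT1 stood at 56.1 against 2.62 and 4.68 against 0.383 CPM, STMN2 at 7.38 against 0.875 and COL3A1 at 184 against 56.6. Cluster 6, unnamed DMSO cells, had TBX18, NR2F2, TCF21 and SHOX2 at 40.6, 40.3, 337 and 6.95 CPM. Of 6 genes, 5 (SHOX2, ISL1, NR2F2, GHRH and TRH, not TBX18) stood above 1.5 times the higher of clusters 9 and 6. Doublets of those clusters alone would not give this. But SHOX2, GHRH and TRH were picked as leading genes of cluster 10, so only ISL1 and NR2F2 stand apart from that choice. On their own they are fewer than the test asked for, and doublets with other clusters were not tried, so doublets are not excluded. ISL1 had 16.4 CPM in cluster 6, GHRH 6.32 and TRH 53.8. TCF21, WT1, STMN2 and COL3A1 lay between both clusters, and for them the source was not tested.

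USP18 was 24.7-fold higher with CHIR in CM-like cells, while 6 other interferon-stimulated genes had a median log2 ratio of −1.57, with 1 higher and 4 lower.

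GAS5, SNHG19 and SNHG3 host small nucleolar RNAs, and their spliced transcripts are broken down by nonsense-mediated decay. One hypothesis was a rise of such host genes as a class. The other 13 host genes had a median log2 ratio of 0.83 for CHIR over DMSO in CM-like cells, with 8 higher and 0 lower, and 1.09 in endoderm-like cells, which is consistent with it. Reduced nonsense-mediated decay predicted a shift of its factors and known targets, whose median was 0.0877 in CM-like cells, 0.35 in endoderm-like cells (0.0754 relative to all genes) and 0.38 over all cells. The CM-like median lay below the bound set beforehand against this explanation. That bound took no account of spread, and these 11 genes went both ways in CM-like cells, from −2.10 to 0.82. No conclusion is drawn for that reason, and this explanation cannot be told apart from others.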
